A study of Mus musculus with 6 samples.

How the data were processed

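Total RNA of back-skin epidermis from 6 mouse embryos of the C57BL6 strain at embryonic day 17.5 was profiled on Illumina bead arrays, 3 wild type and 3 from a Harlequin Ichthyosis model. Per the labels' protocols, the epidermis was peeled from the dermis after 1 hour in 5 mM EDTA at 37 °C, RNA was isolated with the RNAqueous kit and checked on a Bioanalyser, and 500 ng was amplified and biotin-labelled with the Illumina TotalPrep kit. The version of the array, the positions of its probes and a genome build are not given in the sources used here, so no coordinates are printed.

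The deposited raw values are bead summary intensities per probe and array, without background subtraction or normalization, for 45281 probes. BeadStudio is named, without a version, per the submitters' processing notes. Beside each intensity the authors deposited a fraction between 0 and 1 under a column heading that reads as a p-value. The brightest probes stand at 1 and the dimmest near 0, so the fraction was read as 1 minus the detection p, the share of negative control beads that a probe exceeds. The authors also deposited a table of log2 values. Set against the raw intensities, it was found to hold log2 intensity minus the 75th percentile of the array, then minus the median of the 6 arrays for each probe. Recomputed in this way, 100% of its values came out within 0.001 log2 units, and the largest difference was 2.3e-06. Its scale, centring and direction are therefore known from the comparison, and its column medians were 0.26, -0.01 and 0.33 in wild-type arrays 1 to 3 and -0.13, -0.13 and 0.01 in mutant arrays 1 to 3.

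The raw intensities were background-corrected with the normexp method of limma 3.58.1 (the nec function, negative controls inferred from the detection p, offset 16), put on the log2 scale and quantile-normalized in R 4.3.3. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 18358, of which 13743 were detected on all 6 arrays. No pair of arrays held the same values: at most 0.517% of raw intensities were equal between any 2 arrays. Precision is limited by the number of arrays, 3 per group.

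Of the 45281 probes, 35784 carried 1 gene symbol, 0 carried several and 9497 were unnamed. Symbols were brought up to date through Entrez identifiers for 28620 probes and through unversioned accessions for 2637, with the gene table of assembly GRCm38.p6 used for names only, and the platform's symbol was kept for 4527. The kept probes comprised 16276 named probes of 11354 genes and 2082 unnamed probes. A gene with several kept probes was represented by the probe with the highest mean over the 6 arrays. No probe's level was set against another probe's.

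Mutant arrays were compared with wild-type arrays by limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all kept probes, threshold 0.05), without covariates. Fold changes are given with 95% confidence intervals from the same fit. Where no array of a group detected a gene, the fold is a bound: the mean of the detecting group over the mean, in the other group, of the higher of the gene's own value and the lowest value among detected probes on each array.

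Before the data were examined, the test, the filter, the alternatives, the rule for named genes and 33 gene lists were fixed. The lists cover acylceramide and barrier lipid synthesis, cornified envelope and keratohyalin proteins, the late cornified envelope family, the small proline-rich family, desquamation proteases and inhibitors, stress keratins and alarmins, cytokines and chemokines, interferon-stimulated genes, the cell cycle, cholesterol synthesis, fatty acid synthesis, LXR and PPAR targets, the unfolded protein response, the NRF2 oxidative stress response, tight and gap junctions, EGFR ligands and wound response, and hypoxia and glycolysis. They also hold markers of basal and spinous keratinocytes, periderm, hair follicle, dermal fibroblasts, melanocytes, Langerhans cells and macrophages, T cells, neutrophils, endothelium, erythroid cells, skeletal muscle, Schwann cells, Merkel cells and adipocytes, and sex-linked genes. Lists with at least 3 measured genes were tested with camera in limma (preset inter-gene correlation 0.01, adjusted over the 31 lists tested). Within a list, members were also adjusted over the list alone.

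The rule for named genes took the 12 largest rises and the 12 largest falls past the threshold with separated groups (0 genes met this), up to 4 members with the smallest p from each list that passed, and a set of genes fixed in advance whatever their values. Other genes named were chosen after their values were seen, and are introduced as such, apart from the sex-linked genes, of which all measured are given.

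The alternatives were no background correction, normexp with offset 50, median scaling, the authors' table, other detection filters, eBayes with trend and robust estimation, array weights, a block for the replicate number, a block for the prefix of the sample title (bo20 or bo12), each array left out in turn, an estimated inter-gene correlation (statmod 1.5.0), fry, and the mean over a gene's probes. A comparison of only the 4 arrays with prefix bo20 was added after seeing the data. The prefix splits each group into 2 arrays and 1 array, and what it stands for is not given in the labels. The replicate numbers come from the sample descriptions. Deviations from the group means of same-numbered arrays correlated at r = 0.270, 0.462 and 0.538 across probes, which are not independent replicates. Differently numbered arrays of prefix bo20 also correlated, at 0.449 (mutant array 1, wild-type array 2) and 0.191 (mutant array 2, wild-type array 1). Pairs across prefixes stood at -0.621 to -0.312. These values follow the prefix and do not show that the numbers pair arrays, so the number served as a block only as an alternative. Number 3 is also the only number with the prefix bo12, so its correlation does not separate pairing from the prefix.

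Both fits were tested on simulated arrays with the real means and residual spread and 200 probes changed, 50 per size. With all 6 arrays and 18358 probes, 6%, 64%, 82% and 92% of probes changed by 1, 2, 3 and 4 log2 units were recovered, with 4 false calls among 126. Without wild-type array 3 and with 17808 probes, 26%, 72%, 94% and 92% were recovered, with 9 false calls among 151. On simulated values without any effect, camera called 1 of 31 lists, and with 1 list shifted by 1 log2 unit it called 2, the shifted list among them. All simulated probes were drawn independently, with the same spread on every array. The real list genes were correlated (estimated at 0.842 for late cornified envelope genes), and wild-type array 3 stood apart. The simulated rates therefore need not hold for the real arrays.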

Results

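Transcripts were measured in epidermal peels of embryonic back skin, 3 from wild-type mice and 3 from a model of Harlequin Ichthyosis, a severe inherited disorder in which the outer epidermis forms thick plates and the skin barrier fails. The comparison asks how gene expression in the mutant epidermis differs from wild type late in gestation. The labels call the samples of each group biological replicates. Mean raw intensity was 273, 398 and 260 in wild-type arrays 1 to 3 and 417, 463 and 390 in mutant arrays 1 to 3. The arrays detected between 17159 and 18422 of 45281 probes.

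Wild-type array 3 stood apart from the other 5. Across kept probes, which are not independent replicates, its Pearson's r with the others was 0.836 to 0.891, against 0.965 to 0.990 for all other pairs, and the first principal component, with 73.7% of the variance, mainly separated this array. Among 3551 genes with several kept probes, 678 (19.1%) had probes whose deviations from the other arrays lay over 2 log2 units apart in wild-type array 3, compared with 33 (0.929%) in mutant array 3 and at most 9 in any other array. In wild-type array 3, 258 probes were lower by more than 4 log2 units, in mutant array 3, 9 were, and in the remaining arrays 0. Examples chosen after their values were seen are Pabpc1, which encodes a poly(A)-binding protein, with probes at -5.07 and 0.75 from the other arrays, and Eef1b2, a translation elongation factor, with probes at -5.74 and 0.52. Wild-type array 3 was also lower in the lists of stress keratins and alarmins (median deviation -1.72), small proline-rich genes (-1.69) and skeletal muscle (-1.17), and higher in hair follicle genes (0.97), as set out beside those groups. Each deviation is from the median of the other 5 arrays, mutants among them, so it also holds any difference between the groups. Wild-type arrays 1 and 2 deviated by -0.607 and -0.445 in stress keratins and alarmins. In small proline-rich genes they deviated by -0.527 and -0.489.

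**Figure D1:**
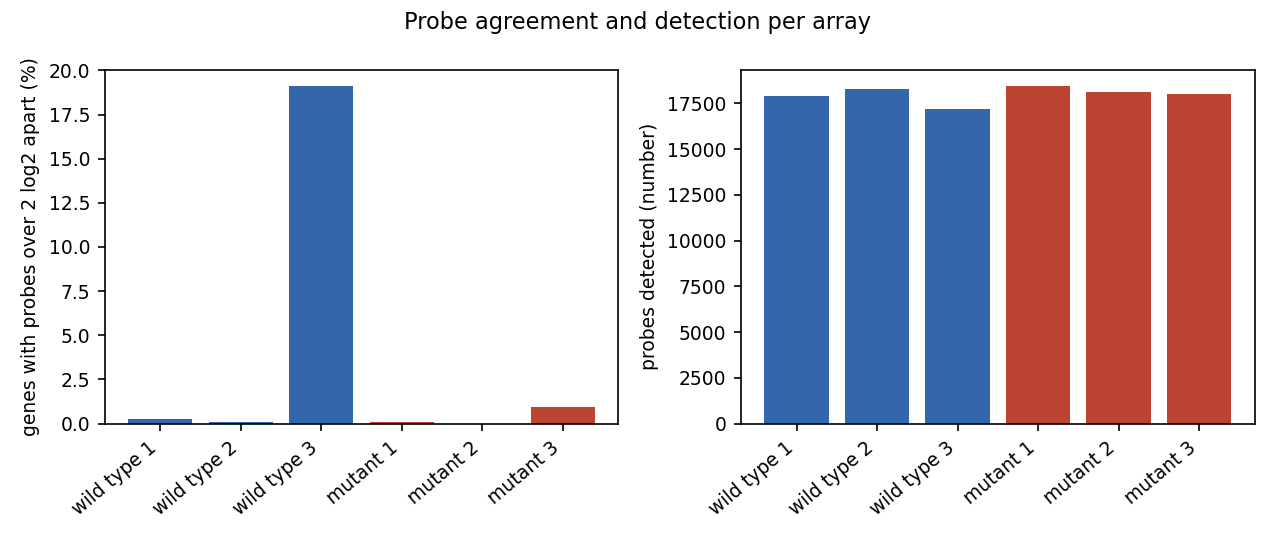
Left, the share of the 3551 genes with several kept probes whose probes deviated over 2 log2 units apart from the other arrays, in percent, and right, the number of probes detected, for each wild-type (blue) and mutant (red) array. Wild-type array 3 reached 19.1%, against at most 0.929% in the others, and had the fewest detected probes, 17159.

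Abca12, the lipid transporter of lamellar granules whose loss causes Harlequin Ichthyosis in humans, was examined first, although the labels do not name the mutated gene of this model. Its brighter kept probe (ILMN_2599768) read 7.15, 7.84 and 4.66 in the wild-type arrays and 5.68, 5.74 and 4.86 in the mutant arrays, a log2 difference of -1.12 (SE 0.78, limma adjusted p = 0.791). Without wild-type array 3 the difference was -2.11 (adjusted p = 0.103), and the adjusted p ranged from 0.0424 to 0.998 over the other settings. Within title prefixes it was -1.79 for bo20 and 0.20 for bo12. A second kept probe (ILMN_1228438) pointed the other way, at 1.04 (SE 0.55, adjusted p = 0.791), and another was not detected on any array. Where the probes lie relative to the mutation is not given in the sources used here, so these values do not check the labels.

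Of the 18358 probes tested, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.0818. That value was shared by genes including Csta3, a stefin-type protease inhibitor, Ccl2, a monocyte chemoattractant, Ccl9, another chemokine, and Clec4d, a myeloid lectin receptor. Apart from Ccl2 these were chosen after their values were seen. At an unadjusted p under 0.05 there were 1077 probes, 454 higher and 623 lower in the mutants, where 917.9 are expected by chance. The mutant and wild-type values did not overlap for 2442 probes (13.3%; chance gives 10%), 1033 higher and 1409 lower. Without wild-type array 3, 49 of 17808 probes passed, 33 higher and 16 lower. All 49 had the same sign with all 6 arrays, which the many arrays shared by these fits nearly ensured. The detection filter was applied anew to the remaining arrays. Probes detected only in wild type could then not be kept, whereas those detected only in mutants could, so the filter favours higher over lower calls. With array weights, which gave wild-type array 3 a weight of 0.112, 129 probes passed, and with the title prefix as a block 48 did. Of the 31 gene lists tested, 11 passed with the preset correlation, 10 higher and 1 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.0846). Without wild-type array 3, 10 lists passed, 7 of them the same, and again 0 passed with an estimated correlation.

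**Figure D2:**
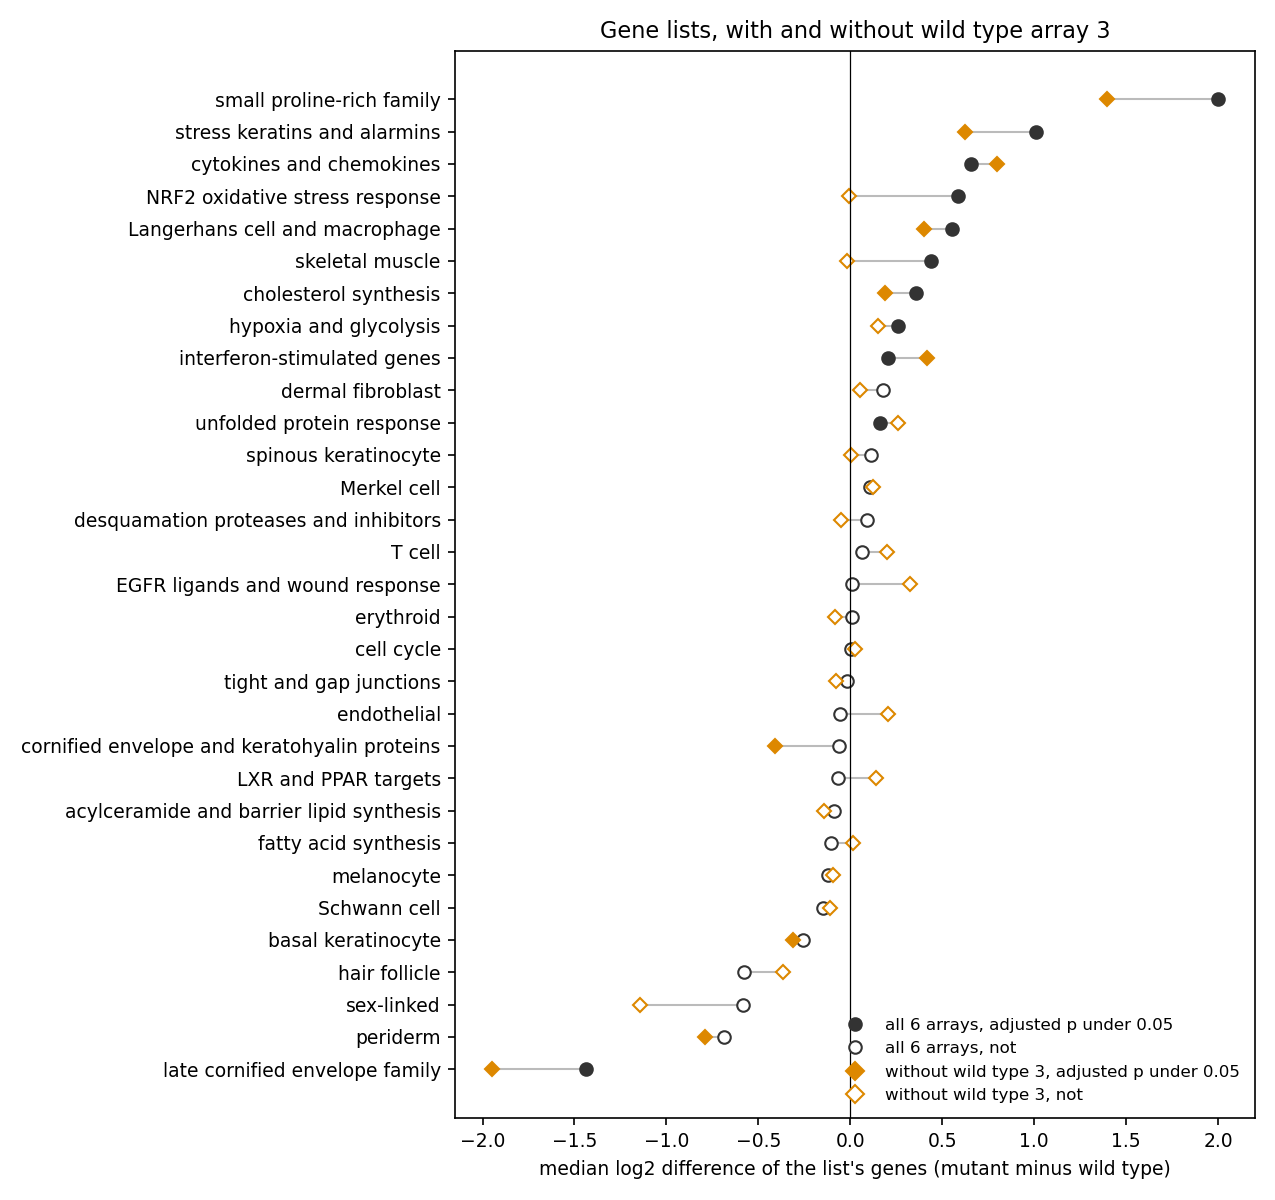
Median log2 difference of each tested gene list (mutant minus wild type) over all 6 arrays (circles) and without wild-type array 3 (diamonds), filled where limma's list test had an adjusted p under 0.05. Small proline-rich genes lie highest (2.00 and 1.40) and late cornified envelope genes lowest (-1.44 and -1.95).

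Krt16 and Krt6b, keratins that keratinocytes make on wounding and in hyperproliferative skin, were 14.3-fold (95% interval 3.45 to 59.5) and 9.94-fold (4.57 to 21.7) higher, with log2 levels of Krt16 of 10.12 ± 1.95 in wild type and 13.96 ± 0.20 in mutants (SD, n = 3 each). The mutant values of Krt16 lie near the top of the array range, so its fold can be compressed. Krt17, a further stress keratin, chosen after its value was seen, differed by -0.09 (SE 0.23). S100a8 and S100a9, whose products form the alarmin calprotectin, were 7.55-fold (2.87 to 19.9) and 5.94-fold (2.11 to 16.7) higher. Saa3, an acute-phase protein, and Slpi, a protease inhibitor of secretions, were 5.57-fold (3.30 to 9.39) and 4.80-fold (2.39 to 9.67) higher. For each of Krt16, Krt6b, S100a8, S100a9, Saa3 and Slpi all 3 mutant values lay above all 3 wild-type values, while limma's adjusted p over all probes was 0.101 to 0.454. As a group, the 22 measured stress keratins and alarmins rose (median 1.01, or 0.95 with 2 genes undetected in wild type at their bounds; adjusted p = 6.89e-10), with adjusted p = 0.329 with an estimated correlation, and had 18 values above 0 and 4 below. None passed over all probes, and 8 passed adjusted over the list alone, all higher. Its median ranged from 0.60 to 1.48 over the other settings. This list deviated by -1.72 in wild-type array 3, and its median was 0.71 within bo20 and 1.45 within bo12. Without the array the median was 0.63 (adjusted p = 4.62e-08; 1.67e-10 to 0.329 over all other settings), and Krt16 (6.55-fold, adjusted p = 0.0231), Krt6b (6.96-fold, 0.0372), S100a8 (4.55-fold, 0.032) and Saa3 (5.98-fold, 0.0463) rose past the threshold, while S100a9 was 3.52-fold higher and did not pass (0.14). Over the other settings the adjusted p of Krt16 ranged from 0.0101 to 0.998. With the title prefix as a block in limma, Krt6b, S100a8, S100a9 and Saa3 passed (adjusted p = 0.0318 to 0.0414), and Krt16 (0.108) and Slpi (0.114) did not. Krt6a, a close relative of Krt6b, did not pass the detection filter.

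The 11 measured small proline-rich genes, which encode cross-bridging proteins of the cornified envelope, rose as a group (median 2.00, adjusted p = 1.56e-09; adjusted p = 0.329 with an estimated correlation), with all 11 values above 0. The log2 differences of Sprr2e, Sprr2d, Sprr1b and Sprr2b were 2.45 (SE 0.66), 2.29 (SE 0.50), 2.11 (SE 0.60) and 2.00 (SE 0.42). Sprr2e and Sprr1b stood at 1.75 and 1.40 without wild-type array 3. None passed over all probes, and 7 passed adjusted over the list alone. The Sprr2 members are nearly identical in sequence, so their probes may read one another's transcripts and the single values are uncertain. The median ranged from 1.26 to 2.38 over the other settings. The family deviated by -1.69 in wild-type array 3, with medians of 1.91 within bo20 and 1.65 within bo12, and without that array its median was 1.40 (adjusted p = 7.77e-07; 1.46e-12 to 0.329 over the other settings).

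**Figure D3:**
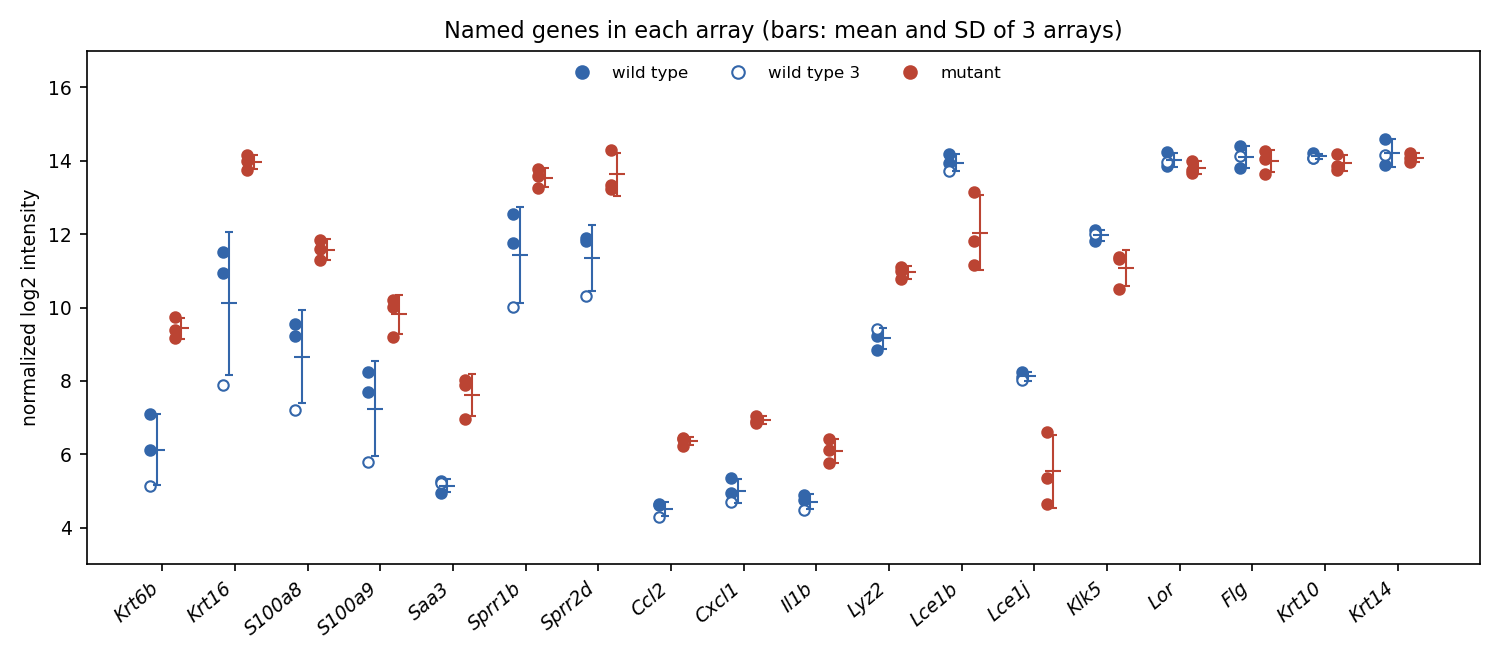
Normalized log2 intensity of named genes on each wild-type (blue) and mutant (red) array, with the mean and SD of the 3 arrays of a group; open circles mark wild-type array 3. Krt16 lies at 13.96 ± 0.20 in mutants and 10.12 ± 1.95 in wild type, Lce1j at 5.53 ± 0.99 and 8.12 ± 0.11, and Krt14 at 14.09 ± 0.13 and 14.21 ± 0.37.

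Ccl2, which draws monocytes, was detected on no wild-type array and on all 3 mutant arrays, at least 2.90-fold higher (adjusted p = 0.0818). Cxcl1, a neutrophil attractant, was 3.82-fold (95% interval 2.60 to 5.61) higher, Cxcl16, a scavenger receptor and chemokine, 3.16-fold (2.14 to 4.66), Ccl7, a second monocyte attractant, 2.92-fold (1.95 to 4.38), and Il1b, an early inflammatory cytokine, 2.62-fold (1.74 to 3.93). The group values of all 5 did not overlap. The 19 measured cytokines and chemokines, of 35 on the array, rose as a group (median 0.66, or 0.53 with undetected genes at their bounds; adjusted p = 1.31e-08, and adjusted p = 0.0846 with an estimated correlation), 15 above 0 and 4 below. The median ranged from 0.11, without a detection filter, to 0.95 over the other settings. None passed over all probes and 10 passed adjusted over the list alone, all higher. The fry test, which asks whether a list's own genes move one way on balance, gave 0.000336. The list median was 0.67 within bo20, 0.74 within bo12 and 0.80 without wild-type array 3 (adjusted p = 7.4e-08), where Ccl2 (0.0294), Cxcl1 (0.0356), Cxcl16 (0.043) and Ccl7 (0.0494) rose past the threshold. Over the other settings the list's adjusted p ranged from 1.21e-09 to 0.0846.

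Markers of Langerhans cells and macrophages, the resident phagocytes of skin, rose as a group (median 0.55, adjusted p = 6.47e-08; adjusted p = 0.329 with an estimated correlation), with all 17 measured genes above 0. Lyz2 and Lyz1, the lysozymes of myeloid and Paneth cells, were 3.47-fold (2.36 to 5.09) and 3.50-fold (2.12 to 5.80) higher. They are nearly identical, so each may read the other. Aif1, a macrophage calcium-binding protein, and Cd74, the invariant chain of antigen presentation, differed by 0.61 (SE 0.27) and 0.70 (SE 0.32). None passed over all probes, and 2, the lysozymes, passed adjusted over the list alone. The median ranged from 0.26 to 1.00 over the other settings. It was 0.51 within bo20, 0.56 within bo12 and 0.40 without wild-type array 3 (adjusted p = 7.4e-08; 1.66e-10 to 0.329 over the other settings), where Lyz2 (adjusted p = 0.0329) and Lyz1 (0.043) rose. The other kept probe of Lyz2 (ILMN_2939681) gave 1.41 with all arrays and 0.53 without wild-type array 3, and passed in neither. Of 4 measured T cell genes, 2 were above 0 and 2 below (median 0.06, mean -0.07, test direction lower, adjusted p = 0.928), and only 2 neutrophil genes were measured (median -0.14, not tested).

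Interferon-stimulated genes rose as a group by a small amount (15 measured, median 0.20, adjusted p = 0.0135; adjusted p = 0.645 with an estimated correlation). Oasl2, an antiviral synthetase-like protein, and Irf1, an interferon regulatory factor, were 2.70-fold (1.61 to 4.54) and 1.98-fold (1.38 to 2.84) higher, and both passed adjusted over the list alone. Ifit3, an antiviral effector, differed by 0.77 (SE 0.33) and Stat2, a transducer of interferon signals, by -0.66 (SE 0.35). With all arrays members thus went both ways, 10 above 0 and 5 below. Without wild-type array 3, 6 members passed adjusted over the list alone, all higher, and Stat2 stood at -0.33. The median ranged from 0.05 to 0.79 over the other settings, and the call also ended with fry (0.73), in the authors' table (0.125), with probes detected on all 6 arrays (0.0742), and without wild-type array 1 (0.162) or wild-type array 2 (0.325). Interferon genes deviated by 0.48 in wild-type array 3. Without it the median was 0.42 (adjusted p = 3.71e-07; 3.71e-07 to 0.73 over the other settings), and within title prefixes it was 0.40 for bo20 and -0.31 for bo12.

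Late cornified envelope genes, which encode small proteins added to the envelope as cornification ends, fell as a group (16 measured, median -1.44, adjusted p = 2.64e-05; adjusted p = 0.645 with an estimated correlation). The log2 differences of Lce1j, Lce1a2, Lce1e and Lce1b were -2.59 (SE 0.47), -2.53 (SE 0.59), -2.27 (SE 0.51) and -1.91 (SE 0.49), each with all mutant values below all wild-type values; Lce1a2 and Lce1b read near the top of the array range in wild type, where a fold can be compressed. None passed over all probes, and 10 passed adjusted over the list alone, all lower, from the Lce1 members and Lce3a. Lce3b, Lce3c and Lce3f, chosen after their values were seen, had values of 2.10, 1.41 and 1.75, which did not pass, and of 0.97, 1.05 and 0.65 without wild-type array 3. These genes are close copies of one another, so single members are uncertain. The list mean of mutant array 2 (10.99) lay above that of wild-type array 3 (9.82; exact permutation p = 0.2 for the list means). The median was -0.87 without mutant array 3 and -1.95 without wild-type array 3 (adjusted p = 7.4e-08; 5.07e-18 to 0.645 over the other settings), and within prefixes it was -1.32 for bo20 and -2.22 for bo12.

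Loricrin (Lor), filaggrin (Flg), Krt1 and Krt10, major structural proteins of the upper epidermis, differed by -0.22 (SE 0.22), -0.12 (SE 0.26), 0.41 (SE 0.20) and -0.19 (SE 0.21). Their probes read near the top of the array range, where a change can be compressed. Involucrin (Ivl), an early envelope precursor, differed by 1.49 (SE 1.21), and by -0.08 without wild-type array 3, while its other kept probe (ILMN_2733290) gave 0.76 (SE 0.39) and 0.48. The 21 measured cornified envelope and keratohyalin genes had a median of -0.06 (adjusted p = 0.635; 0 passed adjusted over the list alone). The list fell without wild-type array 3 (median -0.41, adjusted p = 0.0191; 0.00813 to 0.992 over the other settings), but had adjusted p = 0.696 there with an estimated correlation.

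Genes of acylceramide and barrier lipid synthesis, the pathway that builds the extracellular lipids of the stratum corneum, did not pass as a group (24 measured, median -0.09, adjusted p = 0.515; 0 adjusted over the list alone). Cers3 and Elovl4, which make very long ceramide chains, differed by 0.85 (SE 0.48) and 0.01 (SE 0.22), Ugcg, the glucosylceramide synthase, by 0.26 (SE 0.24), and Alox12b, a lipoxygenase of bound ceramides, by -0.54 (SE 0.24). Among 22 desquamation proteases and inhibitors the median was 0.09 (adjusted p = 0.828), and members moved apart: adjusted over the list alone, Prss8, a membrane-anchored channel-activating protease, fell by 1.47, while Serpinb6c (1.13), Klk6 (1.34) and Ctsc (0.84), a serpin, a kallikrein and a cathepsin, rose. These 4 were chosen after their values were seen. Klk5 and Klk7, which cleave corneodesmosomes, differed by -0.90 (SE 0.29) and 1.00 (SE 1.37), and their inhibitor Spink5 by 0.51 (SE 0.87). The values of Klk7 and Spink5 were -0.64 and -0.30 without wild-type array 3.

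Basal keratinocyte genes had a median of -0.26 over 16 measured (adjusted p = 0.099), with Krt5 and Krt14, the basal keratin pair, at -0.57 (SE 0.24) and -0.13 (SE 0.25). Krt14 read near the top of the array range, where a change can be compressed. The list fell without wild-type array 3, which deviated by 0.44 (median -0.31, adjusted p = 0.00118; 0.00118 to 0.369 over the other settings), but had adjusted p = 0.23 there with an estimated correlation. Spinous keratinocyte genes had a median of 0.11 (14 measured, adjusted p = 0.475). Periderm markers, the keratins of the transient outer fetal layer, had a median of -0.69 over 6 measured (adjusted p = 0.0688), with Krt23, chosen after its value was seen, at -1.92 (SE 0.49) and past adjusted over the list alone. With the replicate number as a block the periderm list fell (adjusted p = 0.0368), as it did without wild-type array 3 (median -0.79, adjusted p = 0.0349; 0.000614 to 0.574 over the other settings), but with an estimated correlation it had adjusted p = 0.356 on all arrays and 0.384 without that array. Hair follicle genes had a median of -0.58 over 18 measured (adjusted p = 0.105), and fell with the replicate number as a block (adjusted p = 0.007), with adjusted p = 0.645 with an estimated correlation and no block. Hair follicle genes deviated by 0.97 in wild-type array 3, and without it the median was -0.36 (adjusted p = 0.15; 7.97e-05 to 0.645 over the other settings). Cell cycle genes had a median of 0.00 (24 measured, adjusted p = 0.775).

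Cholesterol synthesis genes rose together by a small amount (18 measured, 15 above 0, median 0.36, adjusted p = 0.00408; adjusted p = 0.34 with an estimated correlation). Cyp51, Nsdhl, Pmvk and Lss, enzymes of the sterol pathway, differed by 0.66 (SE 0.32), 0.43 (SE 0.24), 0.40 (SE 0.21) and 0.40 (SE 0.21), and 0 passed adjusted over the list alone. The median was 0.23 within bo20 and 0.21 within bo12, and 0.19 to 0.92 over the other settings. Sterol genes deviated by -0.23 in wild-type array 3, and without it the median was 0.19 (adjusted p = 0.0484; 0.000677 to 0.34 over the other settings).

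The NRF2 oxidative stress genes rose as a group (14 measured, median 0.59, adjusted p = 0.00408; adjusted p = 0.356 with an estimated correlation), with members on both sides. Adjusted over the list alone, Gsta4, a glutathione transferase for lipid aldehydes, rose by 1.42 and Hmox1, heme oxygenase 1, fell by 1.52, while Nqo1, a quinone reductase, and Slc7a11, the cystine transporter, stood at 1.07 (SE 0.34) and 0.81 (SE 0.25). The NRF2 genes deviated by -0.57 in wild-type array 3, with medians of 0.07 within bo20 and 0.89 within bo12, and without it the call was lost (median -0.01, adjusted p = 0.286; 0.000218 to 0.534 over the other settings), as it was with array weights, with fry and on the 4 bo20 arrays.

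Hypoxia and glycolysis genes also rose (17 measured, 16 above 0, median 0.26, adjusted p = 0.00408; adjusted p = 0.356 with an estimated correlation and 0.0714 without wild-type array 3), with Egln3, an oxygen-sensing hydroxylase, 2.82-fold higher (1.01 to 7.86), and Pfkp and Pgk1, glycolytic enzymes, and Vegfa, an angiogenic factor, at 0.66 (SE 0.31), 1.87 (SE 1.26) and 1.31 (SE 0.85). Egln3 was 1.69-fold higher and Pgk1 and Vegfa stood at 0.23 and 0.21 without wild-type array 3. A dimmer kept probe of Pgk1 (ILMN_2797973) gave 1.01 (SE 0.29) and, without that array, rose by 1.36 (adjusted p = 0.0464). A second kept probe of Egln3 and of Vegfa had the opposite sign, and 0 genes passed adjusted over the list alone. The median was 0.24 within bo20 and 0.20 within bo12, and without wild-type array 3, which deviated by -0.37, it was 0.15 (adjusted p 0.000677 to 0.448 and median 0.14 to 0.68 over the other settings). The unfolded protein response rose narrowly (19 measured, median 0.16, adjusted p = 0.0499; adjusted p = 0.34 with an estimated correlation; 0 adjusted over the list alone), with the chaperone Hsp90b1 at 0.57 (SE 0.24), Asns, asparagine synthetase, at 1.65 (SE 0.81), the co-chaperone Dnajb9 at 1.57 (SE 0.80) and Chac1, a glutathione-degrading enzyme, at 0.79 (SE 0.46). Asns and Dnajb9 stood at 0.65 and 0.63 without wild-type array 3. With fry the list had adjusted p = 0.0338, and its median was 0.05 to 0.71 over the other settings. The call also ended with median scaling (0.126) and without any 1 of wild-type arrays 1, 2 or 3 or mutant array 1 (highest adjusted p = 0.142; 0.00988 to 0.34 over the other settings).

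Further metabolic and signalling lists did not pass. Fatty acid synthesis had a median of -0.10 (adjusted p = 0.818). LXR and PPAR targets had a median of -0.07, a mean of 0.11 and a test direction of higher (adjusted p = 0.775), and tight and gap junctions a median of -0.02, a mean of 0.11 and the same direction (adjusted p = 0.804). EGFR ligands and wound response genes had a median of 0.01 (adjusted p = 0.515). Among them Epgn, the EGFR ligand epigen, chosen after its value was seen, was 2.50 higher (SE 0.40) and passed adjusted over the list alone (over all probes, adjusted p = 0.152).

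Transcripts of cells other than keratinocytes were abundant in both groups. Hba-a1, a globin chain, read 14.38 in wild type and 14.43 in mutants, Col1a1, a dermal collagen, differed by 0.01 (SE 0.27) and Myl1, a muscle myosin light chain, averaged 13.95 and 14.13. These genes were chosen after their values were seen. Hba-a1 and Myl1 read near the top of the array range, where a difference between the groups can be compressed. Skeletal muscle genes rose as a group (15 measured, all above 0, median 0.44, adjusted p = 0.00408; adjusted p = 0.725 with an estimated correlation), with Ckm, muscle creatine kinase, Myh8, perinatal myosin, Mylpf, a myosin light chain, and Tnni2, a troponin, at 0.46 (SE 0.33), 0.32 (SE 0.26), 0.47 (SE 0.38) and 0.51 (SE 0.42). None passed adjusted over the list alone. Muscle genes deviated by -1.17 in wild-type array 3, with medians of 0.07 within bo20 and 1.10 within bo12, and without it the direction turned (median -0.02, adjusted p = 0.972; 7.05e-05 to 0.972 over the other settings). The muscle call also ended without mutant array 2 (0.121), with median scaling (0.396), with array weights (0.562), with fry (0.787) and on the 4 bo20 arrays (0.536). Medians of the other lists were 0.18 for dermal fibroblasts (adjusted p = 0.189; 0.0216 to 0.623 over the other settings, past the threshold in the authors' table and without mutant array 2), -0.12 for melanocytes (0.775), 0.01 for erythroid cells (0.775) and 0.11 for Merkel cells (0.818). The median was -0.05 for endothelium (mean 0.10, test direction higher, 0.818) and -0.15 for Schwann cells (mean 0.22, test direction lower, 0.804). The 2 measured adipocyte genes had a median of -0.13 and were not tested.

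Sex-linked genes split the arrays across the groups. Eif2s3y and Kdm5d, on the Y chromosome, read 8.09 and 5.94 in wild-type array 1, 8.56 and 6.13 in wild-type array 2 and 8.78 and 5.97 in mutant array 1, against at most 4.99 and 4.59 in wild-type array 3 and mutant arrays 2 and 3. Xist, the RNA of the inactive X chromosome, was 2.75 higher in the mutants by its representative probe (ILMN_2475156, SE 0.66), which passed adjusted over the list alone. Another kept Xist probe (ILMN_1224091) gave 2.63, whereas 2 more (ILMN_3123341 and ILMN_3022688) gave 0.17 and 0.13, with 7.33 and 8.30 in wild-type array 3. The 3 measured sex-linked genes had a median of -0.58, a mean of 0.40 and a test direction of higher (adjusted p = 0.635). High Y-linked levels thus occurred on 2 wild-type arrays and 1 mutant array. Without wild-type array 3, every wild-type array left read high, while mutant arrays 2 and 3 read low. Calls made without that array therefore come from a comparison unbalanced by sex, as read from these genes. Among the bo20 arrays, only mutant array 2 read low, so that subset is unbalanced too. The part of sex in those calls was not tested.

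Without wild-type array 3, 23 genes rose and 13 fell past the threshold, but genes detected only in wild type were removed there by the detection filter. Apart from the genes named above, those that follow were chosen after their values were seen. Higher were Csta3 (4.85-fold, adjusted p = 0.0231) and Csta2 (4.53-fold, 0.0444), stefins that are near-identical and so uncertain, Nfkbiz, a nuclear inhibitor-of-NF-kappa-B protein (2.94-fold, 0.0476), Psmb8, an immunoproteasome subunit (2.79-fold, 0.0444), and Selp, the adhesion receptor P-selectin (2.57-fold, 0.0444). Clec4d was detected on no wild-type array and was at least 3.14-fold higher over all 6 arrays (adjusted p without wild-type array 3, 0.0231). Lower were Tesc, a calcium-binding protein (6.79-fold, adjusted p = 0.0231), Adh1, an alcohol and retinol dehydrogenase (4.37-fold, 0.0372), and Bbox1, the last enzyme of carnitine synthesis (3.48-fold, 0.0372). With all 6 arrays the adjusted p of these genes lay between 0.0818 and 0.578. With the title prefix as a block in limma, Csta3, Csta2, Clec4d, Adh1 and Nfkbiz passed (0.0318 to 0.0414). Psmb8 (0.21), Selp (0.0616), Tesc (0.0562) and Bbox1 (0.058) did not pass with that block.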

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

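Tests on only the 4 arrays with title prefix bo20 were chosen after the results were seen; the other settings were fixed in advance. Against 0 probes past the threshold with all arrays in limma (1077 at an unadjusted p under 0.05), 1 passed without background correction (1 higher), 6 in the authors' table (6 higher), 129 with array weights (73 higher, 56 lower), 48 with the title prefix as a block (29 and 19) and 66 on the 4 bo20 arrays (39 and 27). Leaving out 1 array at a time gave 0 to 49 (0 to 33 higher, 0 to 16 lower), the 49 without wild-type array 3 and 0 without any other. The remaining filters, scalings and variance models gave 0. With the replicate number as a block 0 passed (0 higher, 0 lower), Abca12 stayed at -1.12, and 13 lists passed, periderm and hair follicle added; the block changed no other call. The number of lists past the threshold was 9 to 13 across arrays and scalings, 0 with an estimated correlation and 2 with fry. Skeletal muscle ranged from -0.0185, turned in direction without wild-type array 3, to 0.70 when 1 array was left out, and Abca12 reached -1.79 on the 4 bo20 arrays; the cause was not tested. Leaving out 1 array moved Abca12 between -2.11 and -0.48. Of 1162 values of 62 named genes under other settings, 1118 did not pass, as none did with all arrays, and 44 (15 genes) passed. Of the passing values 0 had the opposite sign, and 55 genes kept their sign throughout, in settings that share most arrays. With median scaling the median of all probes was 0.42, against -0.04 with all arrays and quantile normalization, and list directions are read relative to it. The ranges given above for list medians include that setting and its shift. Relative to the median of all genes, interferon-stimulated genes ranged from 0.06 to 0.46 over the other settings. On that scale cholesterol synthesis ranged from 0.19 to 0.49 and the unfolded protein response from 0.17 to 0.37. Genes near background, such as Ccl2, had folds limited by the detection floor.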

Other observations

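The tests of explanations and the counts over splits were chosen after the results were seen, whereas the list tests without wild-type array 3 or with an estimated correlation were planned.

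The following genes, chosen after their values were seen, were among those with the smallest p. Ecm1, an extracellular matrix protein of the upper epidermis, averaged 11.23 ± 0.08 in wild type and 9.26 ± 0.48 in mutants (SD, n = 3 each). Nt5c3, a pyrimidine nucleotidase, averaged 11.34 ± 0.28 and 9.30 ± 0.31, and Cobl, an actin nucleator, 8.78 ± 0.15 and 7.24 ± 0.19. Rpe, an enzyme of the pentose phosphate pathway, and Tlcd4, a membrane protein, were detected on no mutant array and were at least 3.97-fold and 6.49-fold lower. In the other direction, Lypd1, a Ly6-type membrane protein, averaged 6.10 ± 0.45 and 8.66 ± 0.21, and Cyp3a13, a cytochrome P450, 5.74 ± 0.07 and 7.72 ± 0.27. With all 6 arrays and no block none of these passed, but with the title prefix as a block all did (adjusted p = 0.0318 to 0.0484), as did Nt5c3, Cobl, Lypd1 and Cyp3a13 without wild-type array 3 (0.0231 to 0.0464). Ecm1 did not pass there (0.0732), and Rpe and Tlcd4 were not tested there because the detection filter removed them.

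Wild-type array 3 differed from the other 5 arrays. Probes of one gene moved apart by over 2 log2 units in 19.1% of multi-probe genes there, against 0.929% in the next array, which is consistent with shortened RNA or poor amplification in this sample. Cells of another tissue would be expected to dilute keratinocyte genes as far as the 258 probes that lost over 4 log2 units, yet 7 spinous keratinocyte genes away from the floor and ceiling of the arrays (mean log2 level from 6 to 13) had a median deviation of 0.0188 (-4.10 to 1.15), which argues against that source for those probes. A factor shared with mutant array 3, the other array with prefix bo12, cannot be told apart: their deviations correlated at 0.538, but each group holds 1 such array and both carry replicate number 3, so prefix and number are confounded. Sex as read from Eif2s3y is argued against, since wild-type array 3 correlated with arrays on its side at 0.891 at most while the other 5 correlated across sides at 0.965 or more; hair growth stage was not tested.

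Macrophage genes were higher in the mutants. Dermis carried over in the mutant peels cannot be told apart: the macrophage median lay 0.545 above the fibroblast and endothelial genes (two-sided permutation over genes, p = 0.00417), but 0.334 without wild-type array 3 (p = 0.00017), 0.287 without mutant array 2 (p = 0.0434), 0.523 on genes with a mean log2 level from 6 to 13 (p = 0.00815) and 0.311 in the authors' table (p = 0.107). The permutation treats genes as independent, although the estimated inter-gene correlation of the macrophage list was 0.217. Its p-values do not measure the spread between embryos. Blood carried over also stays open, because only 2 of 8 erythroid genes lay away from the floor and ceiling of the arrays. Neither wild-type array 3 alone (adjusted p without it 7.4e-08) nor the 2 lysozyme genes alone (adjusted p without them 3.18e-05, median 0.38 over 15 genes) carried the list. A larger share or activation of myeloid cells in mutant epidermis was not tested, and the list call was lost with an estimated correlation.

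Late cornified envelope genes were lower while small proline-rich genes were higher. Both list tests with the preset correlation passed without wild-type array 3 (larger adjusted p = 7.77e-07). That array alone therefore does not account for those calls. With an estimated correlation neither list passed without it (adjusted p = 0.688 for late cornified envelope and 0.384 for small proline-rich genes). Signal shared by near-identical members cannot be told apart from many separate changes, since the estimated inter-gene correlations were 0.425 and 0.842 and both calls were lost with them. A broad fall of cornification transcripts would not give the rise of the small proline-rich genes. All 11 lay above 0 (median 2.00, and 1.40 without wild-type array 3), which argues against it for that family. For the late cornified envelope genes alone it stays open, because the cornified envelope and keratohyalin list had a median of -0.061 with all arrays and -0.41 without wild-type array 3. A switch between the 2 families, or a delay of late differentiation in the mutants, could give such a pattern and was not tested.

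The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probes past the threshold, which all 10 of 10 splits reached, and the highest other gave 2, namely wild-type arrays 1 and 2 with mutant array 1 against the rest, which follows the Y-linked genes and called Eif2s3y and an unnamed probe. For the gene lists the real split gave 11 and the highest other 8, so 1 of 10 splits reached as many. At an unadjusted p under 0.05 the real split gave 1077 probes and the highest other 2516, from wild-type arrays 1 and 3 with mutant array 3. These arrays had the lowest mean raw intensities (273, 260 and 390, against 398 to 463 in the others). The split thus follows signal level, which is partly confounded with genotype, since wild-type arrays 1 and 3 are among the dim ones. The cause of this structure was not tested. Among the 4 splits that put same-numbered arrays on opposite sides for all 3 numbers, the others gave at most 5 lists and 320 probes. Without wild-type array 3, the real split of the 5 arrays gave 49 probes past the threshold and the highest other 2, but at an unadjusted p under 0.05 it gave 1735 and the highest other 2797, from wild-type array 1 with mutant array 3. Those arrays were again the ones with the lowest mean raw intensities of the 5.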
